A study of Drosophila melanogaster with 2 samples.

How the data were processed

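The data are ChIP-seq peak lists from whole Drosophila melanogaster embryos of both sexes, collected 0 to 14 h after egg laying, from a transgenic line in which the protein encoded by CG3407 carries green fluorescent protein at its C terminus. ChIP-seq sequences the DNA fragments recovered with a protein by an antibody. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp and there were 2 biological replicates, which form 1 group. The labels disagree on what the libraries are: the free-text description calls each an input control, while the assay title and the antibody field name a transcription factor ChIP. The libraries were treated as ChIP libraries, because the deposited peak lists are described as made from these libraries against 1 separate control file.

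The files are lists of intervals on the dm6 assembly. Each replicate has a list of 30000 intervals that mixes peaks with background, a list of 30000 intervals was made from both replicates together, and a list of 4089 intervals holds the peaks kept by the irreproducible discovery rate (IDR), a procedure that compares the ranks of peaks between replicates. These 4089 intervals were the highest of the pooled list by score, so membership does not show that each peak was found in both replicates. Per the file headers, the candidate lists were derived from alignments and the control file, and the IDR list from the candidate lists. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The value used to rank peaks is the deposited score of the peak caller, whose scale is specific to each list; scores were therefore compared only within a list, or by rank. The deposited column of −log10 q values was not used for ranking, since 3363 intervals of the pooled list share its highest value. Read totals were not analysed here, so the depth behind the peaks is unknown and no statement rests on it. Peaks from the control, or from flies without the tagged protein, were not analysed here.

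Genes came from Ensembl release 115 and sequence from the RefSeq copy of the same assembly; transposable elements were left out of the set of transcription start sites (TSSs). A summit within 500 bp of a TSS was called a promoter summit. Other summits went to the first of coding exon, 5' UTR, 3' UTR, non-coding exon, intron and intergenic sequence. A protein-coding gene was called bound, as shorthand for the presence of a peak, when an IDR summit lay within 500 bp of any of its TSSs, and divergent when another gene started upstream on the opposite strand within 1000 bp.

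The background for positions was the 25911 pooled candidates outside the IDR set. Shares carry 95% Wilson intervals, which cover counting error only. Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 7 feature classes, 6 chromosome arms, 24 gene lists, 24 motifs or 6 classes of non-coding feature, with 0.05 as the threshold. Neighbouring peaks and genes that share a promoter are not independent, so these p-values describe the lists rather than new embryos. Promoter shares were also set against 10000 circular shifts of the summits along each arm. Replicates were compared by the share of replicate 1's 4089 highest candidates that overlapped one of replicate 2's by at least 1 bp, with 10000 permutations of ranks, and by Spearman's rho across peaks with 100000 permutations. The difference of median scores between promoter and other peaks was tested with 100000 permutations. Summit position relative to the TSS was tested with an exact binomial test against an even split and, after the data were seen, with Fisher's exact test against other candidates near a TSS.

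Motifs were searched on both strands within 50 bp of each summit, against pooled candidates matched 1 to 1 on promoter class and on GC content in bins of 5 percentage points. Words of 8 bases were ranked on arms 2L and 2R, and the first 10 were tested on 3L, 3R and X. Gene lists, motifs, tests and the rule for named genes were fixed before the data were examined. The rule takes the 25 protein-coding genes at the highest-scoring promoter summits found among the 4089 highest candidates of both replicates, the 5 highest-scoring peaks away from every TSS, CG3407, the 4 highest-scoring members of each list past the threshold, and every Hox gene. A gene that the rule names is not reported here.

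The tests were tried on simulated data. Of 4089 simulated summits, 40.0% were placed at promoters and 40.0% were recovered there. The placed summits sat exactly on TSSs and the others came from candidates away from promoters. This recovery was therefore fixed in advance and checks the counting only. In 100 random splits of the candidates with no true difference, 6 gave a promoter p below the threshold. A word planted in 9.56% of windows ranked first and was recovered in 9.03% of the held-out windows; no motif and no word was called without planting. A planted list of genes was called, and no other list was. The planted word was more frequent than the words reported below, and the planted list was larger than most lists here. Recovery of rarer words, of small lists and of lists of neighbouring genes was not simulated.

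Alternatives were the removal of each replicate (the other replicate's 4089 highest candidates in place of the IDR set), the 2044 highest-scoring IDR peaks, TSS windows of 250 and 1000 bp, TSSs of protein-coding genes alone, other overlap rules, a motif window of 100 bp, flanks centred 500 bp from the same summits as background, the other set of arms for word discovery, and genes with a candidate at a TSS as background for gene lists. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.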

Results

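ChIP-seq peaks of GFP-tagged CG3407 came from 2 biological replicates of whole embryos aged 0 to 14 h. The IDR set held 4089 peaks in 3959 separate regions that covered 1.41 Mb, with a median width of 416 bp. Scores in this list ran from 163 to 23642, with a median of 262. The first question was where the peaks lay and whether both replicates gave the same sites. Bound means here that a peak is present; peaks from flies without the tag were not analysed here.

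The strongest site lay in spen, which encodes a nuclear RNA-binding co-repressor, at 2L:160446–162488 in the annotated 5' UTR, with a score of 23642. The next was intergenic, at 3L:11245891–11246924, 521 bp from the start of lncRNA:CR44713, with a score of 17753. It was followed by an exon of lncRNA:Vinr (X:12750189–12752556, score 10681) and an intron of Sdc, the gene of the cell-surface proteoglycan syndecan (2R:21474729–21475534, score 8635). The fifth peak away from every TSS lay in an intron of gpp, which encodes a histone methyltransferase, at 3R:6425987–6426750 with a score of 6119. Among promoters of protein-coding genes, the highest scores were at SoxN, a Sox-family regulator of neural development (2L:8824868–8825771, score 7980), and at CG4004 (X:12743640–12744627, score 7779). The peaks at spen, CR44713, Vinr, Sdc, SoxN and CG4004 held ranks 1 to 6 in the IDR set and the same ranks in each replicate.

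The next promoters of protein-coding genes by score were px with 2723, CG14100 with 2545, Ugalt, a UDP-galactose transporter gene, with 2441, and the Polycomb group gene ph-p with 2178. They were followed by CG1888, CG18549, the chromodomain protein gene Chro, the arginine methyltransferase gene Art3, PNPase, Fkbp14, mRpL41, CG8320, CenG1A, Tina-1, Tcs5, CG5611, CG9147, RluA-1, CG31145, Toll-7, gish, CG1635 and E23. Scores in this group fell from 2017 at CG1888 to 1352 at E23. Each peak was listed under the gene with the nearest TSS alone. That TSS can lie inside the gene rather than at its outermost start, as at px, gish, ph-p, CG1888, PNPase and Fkbp14. Among the 50 highest peaks, the intervals at CG14100, CG18549, Chro, Art3 and CG8320 also overlap another annotated gene. Intervals of lower peaks, from Tina-1 on, were not checked for such overlap. The summit listed under CG1635 lies in asRNA:CR45190 and outside CG1635. Peaks that meet another gene cannot be credited to the listed gene alone.

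Of the 4089 highest candidates in replicate 1, 77.0% overlapped one of the 4089 highest in replicate 2. Permuted ranks gave a mean of 16.8% and at most 18.8% (one-sided permutation p = 1e-04, the smallest these permutations can give). Of the IDR peaks, 97.1% overlapped a candidate of replicate 1 and 99.6% a candidate of replicate 2. Across the 3953 IDR peaks with a candidate in both, Spearman's rho of the scores was 0.77 and Pearson's r of their log10 values was 0.86 (permutation p for rho = 1e-05, the smallest possible). Each peak took the highest-scoring overlapping candidate of a replicate, so 129 peaks repeat the score pair of another. With the nearest candidate summit within 100 bp and each candidate used once, rho was 0.76 over 3786 peaks, a check chosen after the data were seen. Peaks are not independent replicates. The IDR set was identical to the 4089 highest candidates of the pooled list by score; 76.5% of it overlapped the 4089 highest candidates of both replicates, and 120 of its peaks had no candidate in replicate 1.

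**Figure D1:**
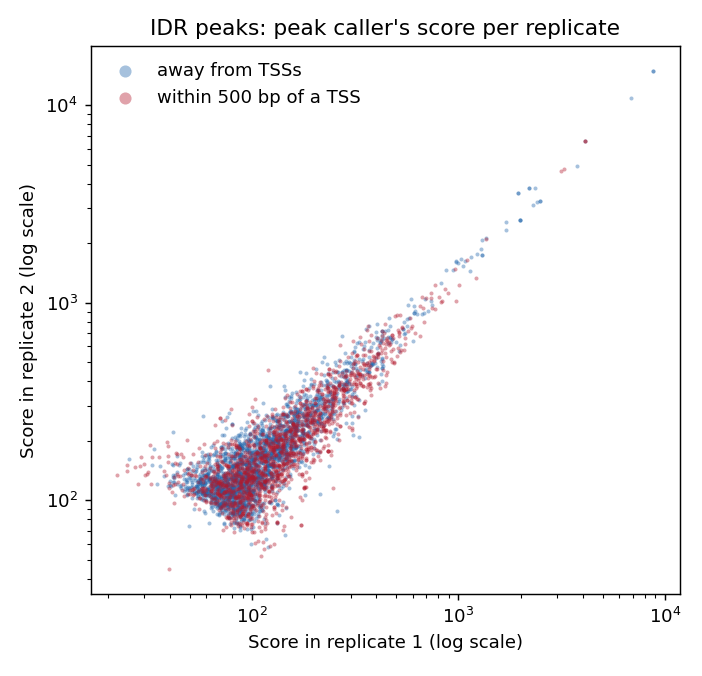
Peak caller's score in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for the 3953 IDR peaks with a candidate in both replicates, with promoter peaks in red and other peaks in blue. The scores rise together, with a Spearman's rho of 0.77.

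The second question was which parts of the genome held the peaks. Promoters held 1715 of the 4089 IDR summits, or 41.9% (Wilson interval 40.4 to 43.5), against 23.3% of the 25911 other candidates (odds ratio 2.37, Fisher's exact p = 2.95e-129). The share was 42.2% ± 0.67 (SD, n = 2) in the highest candidates of the single replicates. Circular shifts of the summits gave a mean of 13.6% and at most 19.3% (permutation p = 1e-04, the smallest possible). Introns held 40.2% of IDR summits against 45.3% of other candidates, and intergenic sequence 15.1% against 23.2%. Coding exons held 0.293% against 3.34%, and 3' UTRs 0.758% against 2.61%. These 4 classes were lower in the IDR set, with adjusted Fisher's exact p from 1.41e-39 for coding exons to 9.92e-10 for introns. Each summit counts in the first class it meets, promoters first, so a higher promoter share by itself lowers the other classes. The lower intron share therefore does not show that peaks avoid introns. Among summits away from promoters alone, introns held a larger share in the IDR set than in other candidates. The 5' UTR class (adjusted exact p = 0.39) and non-coding exons (adjusted exact p = 0.209) did not pass the threshold.

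The promoter share varied with rank. It was 34.0% (Wilson interval 22.4 to 47.8) among the 50 highest peaks, 54.2% (49.6 to 58.8) at ranks 51 to 500, and 38.5% (36.4 to 40.6) at ranks 2001 to 4089. Promoter peaks had a median score of 275.9 and other peaks one of 251.4, a difference of 24.5 (permutation p = 2e-05). With replicate 1 left out the difference was 6.86 (permutation p = 0.0375), and with replicate 2 left out it was 17.9, each on that list's own scale. With a TSS window of 250 bp it was 15.1 (permutation p = 0.00942).

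Promoter summits lay mainly upstream of the gene. Relative to the nearest protein-coding TSS, the median position of 1579 summits was −118 bp, with quartiles of −213.5 and −26.5 bp. Upstream positions made up 79.9% (Wilson interval 77.9 to 81.8; exact binomial p = 3.76e-133 against an even split). Other candidates near a TSS were also more often upstream, at 60.3% (59.0 to 61.6), with a median of −49 bp. The share was higher in the IDR set (odds ratio 2.61, Fisher's exact p = 2.17e-49), a comparison chosen after the data were seen. The median was −115.5 ± 16.3 bp (SD, n = 2) over the single replicates. A summit between the TSSs of a divergent pair counts as upstream whichever TSS is nearer, so an even split is not a neutral reference there. Bound genes were more often divergent than other genes (64.7% against 35.5%), and summits were not split by divergence. The binomial and Fisher's tests therefore cannot separate a preference for upstream positions from a larger share of divergent promoters.

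**Figure D2:**
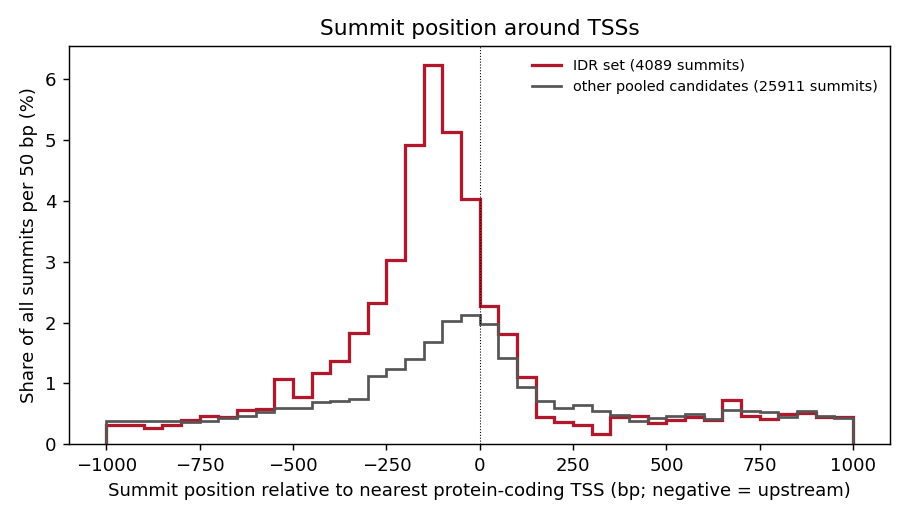
Share of all summits per 50 bp (y axis, %) by position relative to the nearest protein-coding TSS (x axis, bp, negative upstream), for the 4089 IDR summits in red and the 25911 other candidates in grey. IDR promoter summits have a median position of −118 bp.

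The third question was which genes had peaks at their promoters. Of 13945 protein-coding genes, 1964 were bound. Cytosolic ribosomal protein genes had the highest share of the 24 lists, with 64 of 85 bound (75.3%, Wilson interval 65.2 to 83.2) against 13.7% of other genes (adjusted Fisher's exact p = 6.73e-36). The share was 74.7% ± 2.5 (SD, n = 2) over the single replicates. The highest scores among them were 1210 at RpL7 and 1186 at RpS27, and RpL14 had 798.

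Polycomb and trithorax group genes, which maintain silent or active chromatin, were bound in 8 of 17 cases (47.1%, adjusted exact p = 0.00543), with scores of 2178 at ph-p, 797 at brm, 642 at E(z) and 418 at Su(z)2. How many of these 8 genes are neighbours was not counted, so they need not be 8 separate loci. Notch pathway genes were bound in 6 of 14 cases (42.9%, adjusted exact p = 0.0337), among them the co-repressor gene gro with a score of 809, E(spl)m7-HLH with 647, E(spl)m3-HLH with 637 and E(spl)mdelta-HLH with 359. Of these 6 genes, 5 lie in the E(spl) complex on 3R, so they are neighbours. The Notch call was lost without replicate 2 (5 of 14, adjusted exact p = 0.0978), where the odds ratio was 3.54 (95% limits 1.24 to 10.1). Against genes with a candidate at a TSS, of which fewer belong to each list, neither passed the threshold. The Polycomb and trithorax list then had 8 of 13 (adjusted exact p = 0.243), with an odds ratio of 3.03 (95% limits 1.04 to 8.87) after 5.48 (2.17 to 13.8) against all genes. The Notch list had 6 of 9 (adjusted exact p = 0.28), with an odds ratio of 3.64 (0.99 to 13.4) after 4.68 (1.68 to 13).

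Chemosensory, cuticle protein and histone genes were bound less often than other genes. The list of odorant, gustatory and ionotropic receptors, which also takes in odorant-binding proteins, had 2 bound genes of 230 (adjusted exact p = 1.05e-11), Obp99b and Ir60e, the latter with no candidate found at that peak in replicate 1. Cuticle protein genes had 1 of 96 (adjusted exact p = 7.01e-05), Cpr65Av. Histone genes had 0 of 114 (adjusted exact p = 3.32e-07), but most are near-identical copies in which peaks are uncertain. Against genes with a candidate at a TSS, the cuticle (1 of 13, adjusted exact p = 0.28) and histone (0 of 3, adjusted exact p = 0.778) calls were lost, with few genes left in either list.

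The remaining lists did not pass the threshold. All 8 Hox genes (lab, pb, Dfd, Scr, Antp, Ubx, abd-A and Abd-B) had no IDR summit at a TSS, nor did the 8 pair-rule genes, where the Wilson interval reaches 32.4% for each list. Ecdysone response genes had 5 of 12 and heat shock protein genes 8 of 25 (adjusted exact p = 0.0554 for each), insulator and architectural protein genes 5 of 14 (adjusted exact p = 0.0978) and mesoderm and muscle genes 5 of 17 (adjusted exact p = 0.19). These 4 lists changed sides with the setting. The ecdysone list passed without replicate 1 (6 of 12, adjusted exact p = 0.0164) and with TSS windows of 250 bp (adjusted exact p = 0.0249) and 1000 bp (adjusted exact p = 0.0281). It fell to 2 of 12 among the 2044 highest IDR peaks (adjusted exact p = 0.602) and at the canonical TSS alone (adjusted exact p = 0.798). The insulator list passed without replicate 2 (8 of 14, adjusted exact p = 9.95e-04) but had 3 of 14 at the canonical TSS (adjusted exact p = 0.535). The insulator, heat shock and mesoderm lists passed among the 2044 highest IDR peaks, while the mesoderm list had 2 of 17 with a 250 bp window (adjusted exact p = 0.893). None of the 4 passed against genes with a candidate at a TSS. DNA replication and cell cycle genes had 7 of 28. The other housekeeping lists had 13 of 73 for mitochondrial ribosomal proteins, 7 of 44 for translation initiation factors, 11 of 80 for oxidative phosphorylation and 4 of 32 for the proteasome. Segment polarity, dorsal-ventral, neural fate and germline genes had 2 of 14, 2 of 15, 2 of 15 and 2 of 12, and gap and maternal genes 1 of 13. Chorion and yolk protein genes had 0 of 16 and testis-specific genes 0 of 14.

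**Figure D3:**
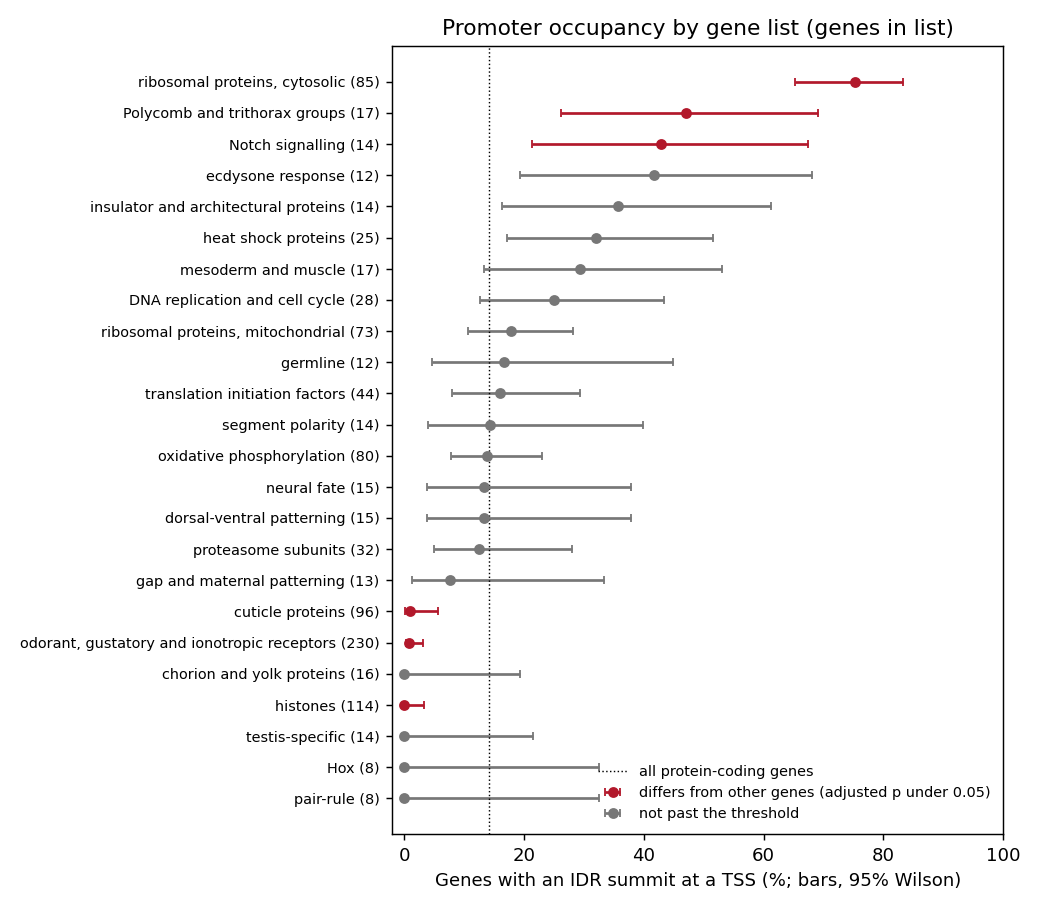
Share of the genes in each of the 24 lists with an IDR summit within 500 bp of a TSS (x axis, %), with 95% Wilson intervals as bars and the number of genes in brackets. Red lists differ from other protein-coding genes; cytosolic ribosomal proteins reach 75.3%.

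Bound genes were more often divergent. Of the 1964 bound genes, 1271 (64.7%) had a gene starting upstream on the opposite strand, against 35.5% of the 11981 other genes (odds ratio 3.33, Fisher's exact p = 9.36e-130). The share was 64.4% ± 1.14 (SD, n = 2) over the single replicates. A summit between a pair of such genes can count for both.

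Among non-coding features, snoRNA genes were near 14 IDR summits, or 0.342% against 0.139% of other candidates (adjusted Fisher's exact p = 0.0191). This call was lost without replicate 1 and among the 2044 highest IDR peaks. Mobile elements were near 1.37% of IDR summits against 2.65% (adjusted exact p = 1.36e-06). Summits near tRNA, snRNA and miRNA genes did not differ past the threshold, and no summit of either set lay near an annotated rRNA gene. Mobile elements and rRNA genes are largely repeated sequence, in which peaks are uncertain, so their low shares say little about binding.

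The X chromosome held 690 IDR peaks, or 16.9% against 16.6% of other candidates (log2 odds ratio 0.03, adjusted Fisher's exact p = 0.808). Without replicate 2 the X was higher, at 0.26 (adjusted exact p = 4.64e-04), and without replicate 1 the value was −0.040. Chromosome 4 held 17 IDR peaks, with a log2 odds ratio of −0.88 that missed the threshold (adjusted exact p = 0.0595). It passed in either replicate alone, at −1.08 (adjusted exact p = 0.0049) without replicate 1 and −1.02 (adjusted exact p = 0.00742) without replicate 2.

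The fourth question was which sequences lay at the summits. GC content within 50 bp was 34.2% at IDR summits and 40.2% at other candidates. Of the 24 known motifs, core promoter motif 7 alone passed the threshold against matched candidates, at 1.59% against 0.758% of summits (adjusted Fisher's exact p = 0.0151). It was not past the threshold without replicate 1, among the 2044 highest IDR peaks or within 100 bp of summits (adjusted exact p = 0.0922). The GAGA element did not pass within 50 bp (1.49% against 1.47%) but did within 100 bp (4.31% against 2.96%, adjusted exact p = 0.033). The Zelda site (0.587% against 0.342%) and the DRE, the element bound by Dref (1.03% against 0.978%), did not pass at either width. Against flanks of the same peaks, which are not matched on GC or promoter class, 7 motifs were higher at summits and 8 lower. The DRE was higher there (1.03% against 0.232%, adjusted exact p = 2.72e-07) and the GAGA element lower (1.49% against 2.56%, adjusted exact p = 3.81e-04).

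Of the 10 words of 8 bases ranked highest on 2L and 2R, 4 were also more frequent on 3L, 3R and X. TATTTACA was at 3.1% of IDR summits and 1.84% of matched candidates (adjusted Fisher's exact p = 0.00953). TGCAAACA was at 1.73% against 0.781%, CTGTTTGC at 1.53% against 0.586% and GTAAATAC at 1.29% against 0.469%. These 4 words overlap in pairs and are not separate findings. TATTTACA shares TATTTAC with the other strand of GTAAATAC, and CTGTTTGC shares TGTTTGC with the other strand of TGCAAACA. Against flanks of the same peaks, TATTTACA passed again (3.1% against 0.961%, adjusted exact p = 5.47e-11), and the other 3 were not among the 10 words ranked highest. The set of words changed with the setting. With discovery on 3L, 3R and X, or among the 2044 highest IDR peaks, no word passed. Some words ranked highest on 3L, 3R and X, then tested on 2L and 2R, shared stretches with those above. CTATTTAC holds TATTTAC, as does AGTAAATA on the other strand, at odds ratios of 2.55 and 1.16 (adjusted Fisher's exact p = 0.132 and 0.614). CAAACAGC shares CTGTTTG with the other strand of CTGTTTGC, at 2.03 (adjusted exact p = 0.405). GTTGTTTA and CACAAATA were below 1, at 0.763 and 0.98. Without replicate 1 ATATTTAC and TATTGACA passed, and without replicate 2 GTAAACAA did. ATATTTAC shares the stretch TATTTAC with TATTTACA and, on the other strand, with GTAAATAC.

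The CG3407 gene itself (2L:3810801–3813410, minus strand) had an IDR peak at 2L:3813253–3813668, 51 bp from its TSS. Its score was 217 and its rank 2707 of 4089. The overlapping peak ranked 2738 in replicate 1 and 2634 in replicate 2. The transgene carries a tagged copy of this gene, and the added copy alone can raise signal there. Binding of the protein to its own promoter is therefore not claimed.

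Several of the strongest peaks lay close together. On the X chromosome, between 12716658 and 12752556, 6 of the 50 highest peaks fell in and beside Smr, which encodes a nuclear receptor co-repressor, CG4004 and Vinr. This counts summits rather than separate regions. The summits with scores of 2040 and 4423 share the interval X:12733705–12736560.

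**Figure D4:**
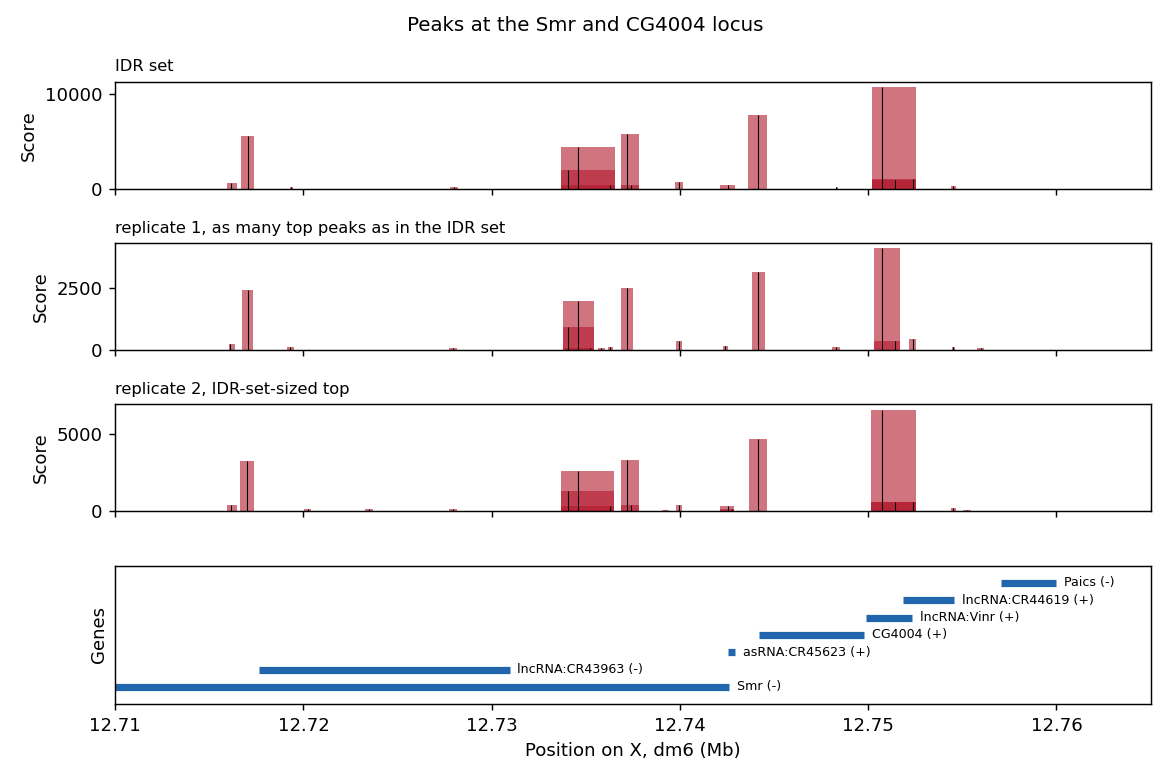
Peaks on the X chromosome (x axis, Mb, dm6) in the IDR set and among as many top candidates of each replicate, with bar height as the score on each list's own scale (y axis), black lines as summits and genes below. The highest peak, with a score of 10681 in the IDR set, lies in Vinr in all 3 lists.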

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

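Gene lists and divergent promoters at the canonical TSS of each gene alone, summit position against other candidates, and the replicate correlation over distinct candidates were chosen after the data were seen; the other alternatives were fixed before. Of all recomputed values, 66 tests kept their direction and side of the threshold, and 18 counts stayed within 1.5 times. In 5 of those 18 the members differed: the gene lists without replicate 1, without replicate 2 and with windows of 250 and 1000 bp, and the motifs within 100 bp. Another 5 values lost the threshold, 3 gained it, 14 counts moved and 1 reversed. The promoter share, the feature classes, the summit position, the divergent share, the replicate overlap and the cytosolic ribosomal protein list kept their direction and side of the threshold under every alternative run for them; the promoter share ran from 31.4% with a 250 bp window to 52.8% with 1000 bp. Among the 2044 highest IDR peaks, 6 gene lists lay above other genes, adding mesoderm and muscle, insulator and heat shock proteins, while 1 non-coding class, 0 motifs and 0 words passed. Against genes with a candidate at a TSS, 1 list lay above and 1 below other genes. Against their own flanks, 15 motifs (7 higher, 8 lower) and 10 words passed, and with discovery on 3L, 3R and X 0 words passed. Leaving out each replicate in turn gave log2 odds ratios of −0.040 to 0.26 for X, reversed without replicate 1, and −1.08 to −1.02 for chromosome 4; 1 to 2 non-coding classes, 0 to 1 motifs and 1 to 2 words passed. The cause was not tested for any of these. Restricting peaks to the main arms was not run, because all peaks lie on them. No paired analysis was possible because there is 1 group. Depth is unknown, so its limit on weak sites cannot be given.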

Other observations

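The tests of the other housekeeping lists and of the number of words searched were chosen after the result was seen. All patterns weighed here were found in the same peaks on which they were tested.

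Of the 14 IDR summits near snoRNA genes, 6 were also within 500 bp of the TSS of a cytosolic ribosomal protein gene, at RpL10Ab, RpL14, RpL17, RpL28, RpS12 and RpS29, so the snoRNA and ribosomal protein results share peaks. Other groups of strong peaks were 4 of the 50 highest at gpp (3R:6410833–6428582), 3 at spen (2L:160446–167015), 3 near scyl (3L:11245891–11257182) and 3 at 2R:13035123–13039509, where no gene is annotated. These are counts of summits, which can share an interval.

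Promoters of cytosolic ribosomal protein genes were bound in 75.3% of cases. Housekeeping promoters in general were bound far less: 35 of 229 genes (15.3%, Wilson interval 11.2 to 20.5) of the 4 other housekeeping lists. Divergent promoters do not account for it, since among genes with no divergent partner 19 of 30 ribosomal protein genes were bound against 674 of 8389 others (odds ratio 19.4, Fisher's exact p = 4.5e-14). Repeated sequence stays open: 100% of the 36-base words at these summits occur once in the genome, but so do 99.8% at 500 other candidates, so this measure would pass for almost any peak. The very high transcription of these genes was not tested and may be a source of signal at any strongly open promoter, so binding by CG3407 remains a hypothesis.

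The strongest peaks lay near one another more often than other IDR peaks. Of the 50 highest, 21 had another within 50 kb in a separate interval, against a mean of 3.11 and at most 13 in 10000 random draws (permutation p = 1e-04, the smallest possible). No minimum gap between intervals was required, so a broad region cut into adjacent intervals can count as neighbours. The draws were not matched on score or width, so the count cannot tell such regions from separate sites. A single library is argued against, since 100% of the 50 peaks were among the 4089 highest candidates of both replicates. Peaks of high pooled score may pass this mark whether they have neighbours or not. The check therefore bears only on presence in both libraries. The share of 76.5% for all IDR peaks includes weaker peaks and is not a like comparison. Repeated sequence stays open for the reason given above, with 100% of 36-base words at the 50 summits found once. Clusters of sites at spen, Smr and gpp are a candidate explanation, but regions that attract signal in any ChIP were not tested, because no peak list without the tagged protein was analysed here.

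The word GTTGCC was picked from exploratory searches of the strongest peaks, and it lay at 54 of the 300 highest peaks away from promoters against 15 of 300 matched candidates (odds ratio 4.07). The check planned for a chance pick came out on the side of chance: among the 2074 weaker peaks away from promoters the odds ratio was 1.18 (Fisher's exact p = 0.311). Counting all 102720 words of 8 searches, the corrected p was 0.065, which misses the threshold. With 1 peak per 20 kb the odds ratio was 4.23, and against the same peaks' flanks it was 3.14, but both checks reuse the peaks in which the word was picked, so a few loci and local base composition stay open. A word limited to the strongest sites is not excluded, but a chance pick may suffice, and no sequence preference is claimed.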
